A study of Mus musculus with 6 samples.

How the data were processed

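Whole olfactory mucosa, the sensory lining of the nasal cavity together with its glands and underlying tissue, was taken from 3 wild-type C57BL/6 mice at postnatal day 11. Each mouse gave 1 library from the closed nostril and 1 from the open nostril, so that the 6 libraries form 3 closed and 3 open. A sheet deposited with the data states that libraries of the same number come from the same mouse. Total RNA was extracted with the Qiagen RNeasy micro kit and prepared with TruSeq, per the labels' protocols. Strand marking and the start and length of the closure are not given in the sources used here.

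The expression values are FPKM per gene as deposited by the authors, that is fragments scaled to transcript length and to the mapped fragments of the library, with 1 column per library. Cufflinks and the mouse genome build mm9 are named in the submitters' processing notes, with no version. The aligner, the annotation and any further scaling between libraries are not given in the sources used here. A deposited sheet gives the count of reads per library as the authors recorded it, without saying whether a read pair counts as 1 or 2. The same sheet gives the fraction of reads aligned, unaligned and taken by abundant sequences, as deposited, which is printed here as a percent. The RNA integrity number and the coverage uniformity are deposited as a score per library, and the 28S over 18S ratio is deposited as a plain ratio. A second deposited sheet holds 1119 olfactory receptor rows, whose FPKM equalled the rows of the table of all genes in every column, so it was used only for this check.

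The table held 24315 rows, of which 3334 were at 0 in all 6 libraries. In 27 rows the gene symbol had turned into a calendar date, and none of these is named here. FPKM are not counts, so genes were compared on log2(FPKM + 1) for the 14788 rows with a mean of at least 1 FPKM over the 6 libraries, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on expression) and Benjamini-Hochberg adjustment at 0.05. A log2 change is closed minus open on that scale, which understates the change of low genes, and it is given with its standard error (SE). Olfactory receptor genes, those whose symbol is Olfr and a number, were fitted separately on log2(FPKM + 0.1), with a mean of at least 0.1 FPKM and adjustment over these 1085 receptors alone. Summed receptor FPKM were compared with a two-sided exact permutation test, whose smallest p is 0.1 with 3 libraries against 3. The spread of the receptor changes was set beside 10000 random gene sets of the same size matched on mean FPKM.

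Before the data were examined, 31 gene lists were fixed (markers of cell types, neuronal functions, metabolic and stress pathways), with 819 entries, of which 809 had a row. Skeletal muscle had fewer than 3 members at 1 FPKM and was not tested. The other 30 lists and the receptor family were tested with camera (limma), with the correlation between genes preset to 0.01, and again with an estimated correlation and with fry. Counts of members past the test are given over all rows tested and adjusted over the list alone. The list of published activity-linked neuronal genes was drawn from the literature on naris closure and neuronal activity, which may include work on these same libraries. Named genes follow a rule fixed at the same time: in each direction the 10 largest changes past the test with no overlap between sides, filled to 10 by the lowest p with no overlap and then described as not past the test, up to 4 members of each list, 5 receptors per direction and 10 genes named whatever their values (Omp, S100a5, Kirrel2, Kirrel3, Gap43, Fos, Egr1, Cyp2g1, Krt5 and Hist2h2be). Genes outside the rule, chosen after their values were seen, are Epha5, Efna5, Taar6, Gm14744, S100a4, Xist, Klk1, Car6 and, among secreted protein genes, Scgb2b27, Scgb1b27, Lcn3, Lcn4, Obp2a, Mup4, Bpifb3, Bpifb4, Bpifb5 and Bpifb6.

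The main comparison was fixed without the mouse as a block, before the sheet on the pairing had been read. The blocked fit is given beside a result where it changes a call. The deviations of same-numbered libraries from their side means correlated at 0.08 for mouse 1, 0.09 for mouse 2 and 0.46 for mouse 3, across genes, against values from -0.25 to 0.13 for libraries of different numbers. Xist, transcribed from the inactive X chromosome, stood at 0.063 and 0.086 FPKM on the closed and open side of mouse 1 and at 28.8 or more in the 4 libraries of the other mice, so that the numbers matched in sex.

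The fits were tested on simulated data before use, with 200 genes changed by known folds in libraries drawn from the real means and variances. So many changed genes ease the adjustment, and where fewer genes change the recovered shares would be lower. The simulated libraries also held no mouse effect and no correlation between genes, so the shares below need not hold for the real libraries. For all genes (14788 rows) the test recovered 38.8% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes, and 6.79% of its calls were false. With the block it recovered 61.2%, 98.5% and 100%, and 13.1% of its calls were false. For the receptors (1085 rows) it recovered 11.9%, 55.2% and 100%, with 4.31% false. A simulated shift of 0.3 on the log2 scale in a list of 40 genes was called by camera with the preset and with the estimated correlation, and none of the other 30 sets was called in either run, in data simulated without correlation between genes.

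Alternatives were other pseudocounts (0.1 and 2, receptors 0.5 and 1), no floor or a floor of 5 FPKM (receptors 0.5), a shift of the libraries to one median, quantile normalization, the replicate block, other variance models and each of the 6 libraries left out in turn. Leaving out rows of microRNAs and other small RNAs was added after 2 such rows had been seen among the calls. Gene models of mm9 were not used here. Which genes lie next to each other was looked up in a GRCm38 annotation, and no coordinates are given. Figures were drawn with matplotlib 3.10.9.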

Results

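Transcripts of the olfactory mucosa were compared between the closed and the open side of mice with 1 naris closed, a manipulation that cuts off odor-laden airflow on that side. It is used to ask which genes depend on olfactory activity. No unoperated mice were sampled, so a lower value on the closed side cannot be told from a higher one on the open side. Effects of closure other than the loss of odor cannot be separated either. Below, "fell" and "rose" mean lower and higher on the closed than on the open side. The 6 libraries came from 3 mice at postnatal day 11, each mouse giving a closed and an open side. Sequencing yielded 24958172, 39595257 and 32719061 reads on the closed side of mice 1, 2 and 3, and 40051026, 33945264 and 43584803 reads on their open side, of which 93.28% to 96.99% were aligned. The RNA integrity number was 10 in every library. Closed replicate 1 was the shallowest and stood apart in its share of FPKM from microRNA and other small RNA rows, 11.3% against 3.47% to 5.27% in the other 5 libraries. Because the deposited values are FPKM and not counts, counting error per gene is unknown and precision rests on the 3 libraries per side.

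S100a5, a calcium-binding protein of olfactory sensory neurons, fell from 2017 ± 77.2 FPKM on the open side to 249.1 ± 47.1 on the closed side (SD, n = 3 each), an 8.09-fold difference. Pcp4l1, a relative of the calmodulin-binding protein Pcp4, fell from 329.3 ± 15.7 to 113.0 ± 6.99 FPKM. Lrrc3b, a leucine-rich repeat membrane protein, fell from 33.8 ± 4.50 to 13.6 ± 1.73 FPKM, and Rasgrp4, an exchange factor for Ras, fell from 4.82 ± 0.687 to 1.21 ± 0.291 FPKM. S100a3, an S100 gene near S100a5 in the GRCm38 annotation, fell from 2.78 ± 0.150 to 0.51 ± 0.214 FPKM, and in every library it stood at 0.13% to 0.24% of the S100a5 value. No protein-coding gene rose.

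The log2 changes were -3.03 for S100a5 (SE 0.19, limma adjusted p = 0.000888), -1.53 for Pcp4l1 (SE 0.12, adjusted p = 0.00379), -1.25 for Lrrc3b (SE 0.14, adjusted p = 0.0389), -1.40 for Rasgrp4 (SE 0.16, adjusted p = 0.0389) and -1.33 for S100a3 (SE 0.15, adjusted p = 0.0447). Each of these genes was lower on the closed side in 3 of 3 mice. With the mouse as a block, limma kept S100a5 (adjusted p = 0.0132) and Pcp4l1 (adjusted p = 0.0354), while the adjusted p was 0.233 for Lrrc3b, 0.239 for Rasgrp4 and 0.19 for S100a3. With each library left out in turn the call of Lrrc3b ended (adjusted p from 0.0646 to 0.121), as did that of S100a3 (0.0825 to 0.183) and, except without closed replicate 1, that of Rasgrp4 (0.093 to 0.166), whereas S100a5 and Pcp4l1 were called under all 17 alternatives.

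**Figure D1:**
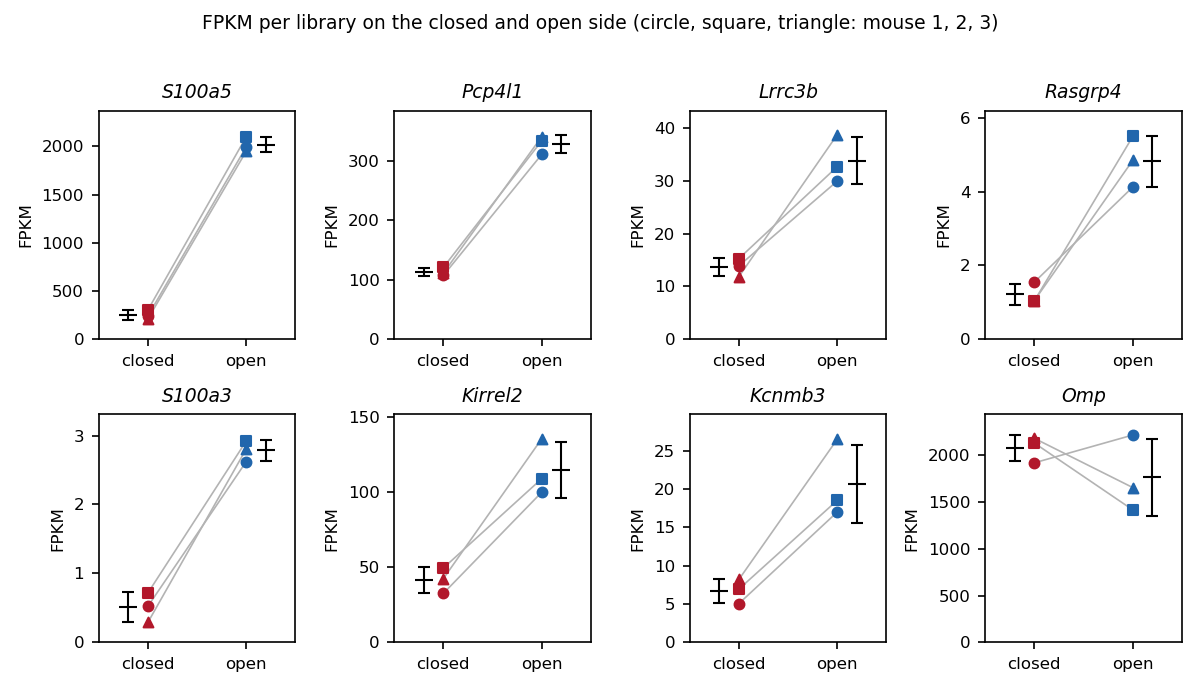
FPKM (linear axes from 0) of 8 genes on the closed (red) and open (blue) side. Each point is a library, grey lines join the sides of a mouse, and black marks give the mean ± SD of 3 libraries; for S100a5 the closed libraries lie between 208.0 and 300.5 FPKM and the open libraries between 1951 and 2102, whereas for Omp the sides overlap.

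Over all 14788 rows tested, limma called 6 that fell and 1 that rose on the closed side at an adjusted p under 0.05, and 215 rows were under 0.05 unadjusted (87 higher, 128 lower). That is a smaller share of the rows than the 0.05 that chance alone would give in independent libraries, which pairs from 1 mouse are not. With the block 351 rows were under 0.05 unadjusted, again a smaller share. The count itself is thus no sign of further changes, and it does not speak against them either. The remaining calls were microRNA rows: Mir6357 was listed at 0 in the 3 closed libraries and at 119.0, 192.3 and 137.4 FPKM in the open ones, and Mir330 was listed at 0 in the 3 open libraries and at 398.8, 197.5 and 204.3 FPKM in the closed ones, so that no fold is given. Such short rows are poorly measured in FPKM, and without them the counts were 6 and 0. The blocked fit called 4 rows that fell and 1 that rose, of which 4 were shared with the fit without the block. Sides did not overlap in 499 rows (3.37%), where chance gives 10% for 3 against 3 if all libraries are independent, which pairs from 1 mouse are not. Within mice, 9.18% of rows were lower and 7.41% higher on the closed side in 3 of 3 mice, where chance gives 12.5% each.

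Next in order among lower genes came Kirrel2 and Kcnmb3. Kirrel2, an immunoglobulin-superfamily adhesion molecule of olfactory axons, measured 41.5 ± 8.46 FPKM in closed and 114.8 ± 18.5 FPKM in open libraries (log2 change -1.45, SE 0.18, limma adjusted p = 0.0592). It was not past the test, and passed it in 3 of 17 alternatives (adjusted p from 0.0194 to 0.268), among them the fit with small RNA rows left out (adjusted p = 0.0293). Kcnmb3, a beta subunit of calcium-activated potassium channels, measured 6.73 ± 1.59 against 20.7 ± 5.09 FPKM (log2 change -1.48, SE 0.20, adjusted p = 0.127) and was past the test in the blocked fit (adjusted p = 0.0354) and in 2 of the other alternatives, the robust variance model (adjusted p = 0.0407) and the blocked fit without small RNA rows (adjusted p = 0.0199), in a range from 0.0199 to 0.516. The row 5730403I07Rik had a log2 change of -0.89 and Gm14743, which lies near the odorant-binding protein gene Obp1a in the GRCm38 annotation, one of -4.41, neither past the test.

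Genes with higher values on the closed side were not past the test, apart from the Mir330 row. Kirrel3, a relative of Kirrel2, measured 26.2 ± 5.04 FPKM in closed and 14.5 ± 1.98 FPKM in open libraries (log2 change 0.80, SE 0.16, limma adjusted p = 0.578). Akr1b3, which encodes aldose reductase, had a log2 change of 1.01 with 11.8 ± 1.56 against 5.40 ± 1.41 FPKM (adjusted p = 0.386). Dcdc2a, a doublecortin-domain gene, had a log2 change of 0.84, the calcium-binding Necab3 one of 0.72, the ectonucleotidase Entpd2 one of 0.81, the active zone gene Rims3 one of 1.12 and the inositol phosphate kinase Itpka one of 0.60. B830017H08Rik stood at 1.05 and Slc23a3 at 0.60. In all of these the sides did not overlap, as the naming rule required.

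Among 28 measured members of the list of published activity-linked neuronal genes, 4 fell over all rows tested (S100a5, Pcp4l1, Lrrc3b and Rasgrp4) and none rose. Adjusted over the list alone, 7 fell and 2 rose: Kirrel2, Sema7a and Epha5 joined the genes that fell, and Kirrel3 and Efna5 were those that rose. With the block, only 2 fell over all rows tested (S100a5 and Pcp4l1). Adjusted over the list alone 8 then fell and 3 rose, Kcnn2 (-0.62) and Pde4a (0.47) being the added ones. Epha5 and Efna5 lay outside the naming rule and were named after their values were seen. The list may rest in part on these same samples, so its direction is not independent evidence. Its median log2 change was -0.09, and camera placed it lower (adjusted p = 3.65e-07 with the preset correlation), a call that was lost with adjusted p = 0.682 with an estimated correlation. The fry test for change in either direction gave an adjusted p of 0.000359.

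Axon guidance and adhesion genes differed in direction. Of 33 measured members none was past the test over all rows, and adjusted over the list alone 4 fell (Kirrel2, Sema7a, Epha7 and Epha5) and 2 rose (Kirrel3 and Efna5). All of these but Epha7 are also in the activity-linked list, so the results of the 2 lists are not independent. The limit given for that list holds here too. With the block Epha5 was no longer past the test over the list alone (adjusted p = 0.0539), which left 3 that fell and 2 that rose. Sema7a, a membrane-anchored semaphorin, measured 22.6 ± 3.23 FPKM in closed and 51.1 ± 14.4 FPKM in open libraries (log2 change -1.11, SE 0.21). The Eph receptors Epha7 and Epha5 had log2 changes of -0.55 and -0.46, and Efna5, an ephrin ligand of such receptors, one of 0.57. Camera did not call the list (adjusted p = 0.452), though it placed it lower without closed replicate 3 (adjusted p = 0.000134) and without open replicate 2 (adjusted p = 0.0165), and the fry test for change in either direction gave an adjusted p of 0.0446.

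Markers of mature olfactory sensory neurons did not follow S100a5. Omp, the olfactory marker protein, measured 2073 ± 138 FPKM in closed and 1759 ± 410 FPKM in open libraries (log2 change 0.26, SE 0.25). Of the 25 members 21 had a log2 change above 0, with a median of 0.23, and the members with the largest t values were Kcnmb3 (-1.48), the sodium-calcium exchanger Slc8a1 (-0.80), the calcium-binding Calb2 (0.53) and the phosphodiesterase Pde4a (0.47). None was past the test over all rows, and Kcnmb3 and Slc8a1 fell adjusted over the list alone. With the block Kcnmb3 was past the test over all rows (adjusted p = 0.0354), and Pde4a rose adjusted over the list alone (adjusted p = 0.0492, against 0.2003 without the block). Odor transduction and cilia genes had a median of 0.08, with 28 of 36 above 0, among them Ano2 (0.48), Stoml3 (0.41) and the channel subunit Cnga4 (0.40). Camera placed both lists higher at the preset correlation (adjusted p = 0.000783 and 0.000163), and both calls were lost with an estimated correlation (adjusted p = 0.806 and 0.768). The calls also ended without closed replicate 3 (adjusted p = 0.901 and 0.298) and without open replicate 2 (adjusted p = 0.918, on the lower side, and 0.391).

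Immature neurons and dividing basal cells differed little. Gap43, a growth cone protein of immature neurons, measured 313.6 ± 20.8 FPKM in closed and 304.8 ± 68.4 FPKM in open libraries (log2 change 0.06, SE 0.18), and turned negative without open replicate 2 (-0.08). The immature neuron list had a median of 0.08 and was called with the block (adjusted p = 0.081 without and 0.0328 with it), though not with the block and an estimated correlation (adjusted p = 0.767). It was also called without open replicate 1 (adjusted p = 7.93e-05) and took the lower side without open replicate 2 (adjusted p = 0.49). The globose basal cell and proliferation list had a median of 0.04 and 22 of 24 members above 0 (camera adjusted p = 0.0201, and adjusted p = 0.806 with an estimated correlation). Its call ended without open replicate 1 (adjusted p = 0.084), open replicate 3 (0.966) or closed replicate 2, where it took the lower side (0.0843), and with quantile normalization (0.0534). Hist2h2be, a histone gene of olfactory neurons, had a log2 change of 0.21 (SE 0.15).

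Immediate early genes, which are transcribed within minutes of stimulation, lay lower on the closed side in 22 of 26 measured members, with a median log2 change of -0.15. None was past the test, over all rows or adjusted over the list alone. Fos measured 11.7 ± 6.04 against 25.03 ± 15.1 FPKM (log2 change -0.91, SE 0.54), Egr1 16.5 ± 7.09 against 27.5 ± 12.2 FPKM (-0.66, SE 0.39) and Dusp1 28.6 ± 4.58 against 47.6 ± 13.7 FPKM (-0.68, SE 0.21). Nr4a1 stood at -0.70, Junb at -0.50 and Maff at -0.36. The sizes depended on single libraries, as Fos, Egr1 and Nr4a1 stood at -1.54, -1.09 and -1.10 without open replicate 1 and at -0.51, -0.41 and -0.40 without open replicate 3, and Junb at -0.83 without open replicate 1 and -0.25 without open replicate 2. Camera placed the list lower at the preset correlation (adjusted p = 3.79e-07), a call lost with an estimated correlation (adjusted p = 0.682).

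Gland and secretory genes split. Obp1a, an odorant-binding protein, measured 30.5 ± 34.5 FPKM in closed and 408.7 ± 132 FPKM in open libraries (log2 change -4.26, SE 0.69, limma adjusted p = 0.261). Lcn11, a lipocalin, stood at -4.08, and the BPI-fold genes Bpifb9a and Bpifb9b at -4.89 and -5.48. None of the 18 measured members was past the test over all rows, whereas these 4 fell adjusted over the list alone (with the block, 5 fell, Ltf being added). The list's median was -0.14 and its mean -1.23, camera placed it lower (adjusted p = 9.96e-07), and the call was lost with an estimated correlation (adjusted p = 0.682). Obp1a and Lcn11 passed the test over all rows without closed replicate 3 (adjusted p = 0.00211 and 0.0166), and Bpifb9a and Bpifb9b without closed replicate 1 (adjusted p = 0.00984 and 0.0379). Under the other alternatives none of the 4 was past it, and the highest adjusted p was 1.

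Supporting cells and horizontal basal cells lay lower by small amounts. Sustentacular cell genes had a median log2 change of -0.13, with 21 of 24 below 0. Among them were the cytochrome Cyp2g1 (1204 ± 124 against 1456 ± 170 FPKM, log2 change -0.27) and the sulfotransferase Sult1c1 (-0.45), while Sult1d1 stood at 0.43. All 13 horizontal basal cell genes were below 0, with a median of -0.22 and with Perp at -0.33, Icam1 at -0.27, Krt14 at -0.27 and Krt5 at -0.04, the last of which turned positive without closed replicate 1 (0.12) and without open replicate 2 (0.03). Xenobiotic metabolism genes, several of which are sustentacular genes, had a median of -0.13, and their call ended without closed replicate 1 (adjusted p = 0.117) and without open replicate 2, where it took the higher side (0.378). The sustentacular call ended without open replicate 2 (adjusted p = 0.493) and the horizontal basal cell call without closed replicate 1 (0.632). Camera called the 3 lists lower (adjusted p = 0.00109, 0.000272 and 0.00598), and none with an estimated correlation (adjusted p = 0.768, 0.768 and 0.806).

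Immune, glial and vascular markers differed in direction. Neutrophil genes lay higher in 16 of 18 members, with a median log2 change of 0.39. Mmp8, a neutrophil collagenase, stood at 0.54, and Ltf, which is also a gland gene, at -0.999. Macrophage genes lay lower in 15 of 17, with Csf1r at -0.23 and Cd68 at -0.21, while Ly6c2, which had the largest t value among them, stood at 0.42. Genes of ensheathing glia and Schwann cells lay lower in 14 of 17, with Fabp7 at -0.52 and S100b at -0.37. Endothelial genes lay lower in 13 of 14, with Kdr at -0.21, and were placed higher without closed replicate 1 (adjusted p = 0.00342). Presynaptic genes had a median of -0.04, with Syt4 at -0.57, Slc17a6 at -0.44 and Syn2 at -0.43, and took the higher side without closed replicate 2 (adjusted p = 0.39). None of these genes was past the test. The camera adjusted p values were 2.98e-05 for neutrophils, 0.00109 for macrophages, 0.0164 for glia, 0.0434 for endothelium and 0.043 for presynaptic genes, against 0.768, 0.768, 0.768, 0.806 and 0.806 with an estimated correlation. Single libraries ended these calls: closed replicate 2 for neutrophils (adjusted p = 0.197), closed replicate 3 and open replicate 2 for macrophages (0.336 and 0.559), closed replicates 1 and 2 and open replicate 3 for glia (0.572, 0.0721 and 0.964), and open replicates 1 and 3 for endothelium (0.29 and 0.735) and presynaptic genes (0.531 and 0.745). The endothelial call also ended at a pseudocount of 2 (adjusted p = 0.054), with no floor on FPKM (0.104), at a floor of 5 FPKM (0.0515) and with quantile normalization (0.0534), the presynaptic call at a pseudocount of 2 (0.0523), with no floor (0.117) and with quantile normalization (0.0534), and the glial call with no floor (0.0616).

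The other lists were not called by camera with all libraries, a pseudocount of 1 and a floor of 1 FPKM. Median log2 changes were -0.06 for cytosolic ribosome, -0.06 for glycolysis, -0.06 for apoptosis, -0.06 for bone, cartilage and fibroblast, -0.05 for hypoxia, -0.05 for microvillous, tuft-like and ionocyte cells, -0.05 for voltage-gated channels (with Kcnn2 at -0.62), -0.04 for unfolded protein and integrated stress response, -0.04 for lymphocytes and plasma cells, -0.03 for interferon response, -0.02 for oxidative phosphorylation, 0.02 for multiciliated cells, 0.03 for erythroid cells and 0.05 for vomeronasal neurons. The camera adjusted p values of these lists ran from 0.081 to 0.927. Among the channels, Kcnk10 stood at 0.39, on the other side from Kcnn2. Cytosolic ribosome genes averaged 8.84 on the log2 scale in closed replicate 3 and 9.23 to 9.60 in the other libraries, and without that library the list was called higher (adjusted p = 1.3e-05). Adjusted over the list alone, Kcnmb3 fell in the voltage-gated channel list and Kirrel3 rose in the vomeronasal list, and with the block Bglap2 (0.71) rose in the bone list. Kirrel3 is also in the activity-linked and axon guidance lists, so its rise is not specific to vomeronasal neurons. Hypoxia genes were called lower with no floor on FPKM (adjusted p = 0.0262) and glycolysis genes at a floor of 5 FPKM (0.0496). Lists called lower with 1 library left out were ribosome (without closed replicate 1, 1.49e-05; closed 2, 0.0107; open 3, 0.00036), oxidative phosphorylation (closed 1, 0.0204; closed 2, 0.0201; open 3, 0.0131), bone (closed 2, 0.0163; open 2, 6.35e-05), voltage-gated channels (closed 3, 0.000105; open 2, 0.00318), glycolysis (open 2, 0.0373; open 3, 0.00332), interferon response (closed 2, 0.00393) and multiciliated cells (closed 2, 0.000819). Those called higher were oxidative phosphorylation (without closed replicate 3, 0.00018), bone (closed 1, 0.0223; open 1, 0.0315), multiciliated cells (closed 1, 0.000405), unfolded protein response (closed 1, 0.0385), interferon response (open 2, 0.0359) and erythroid cells (closed 3, 0.0309).

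**Figure D2:**
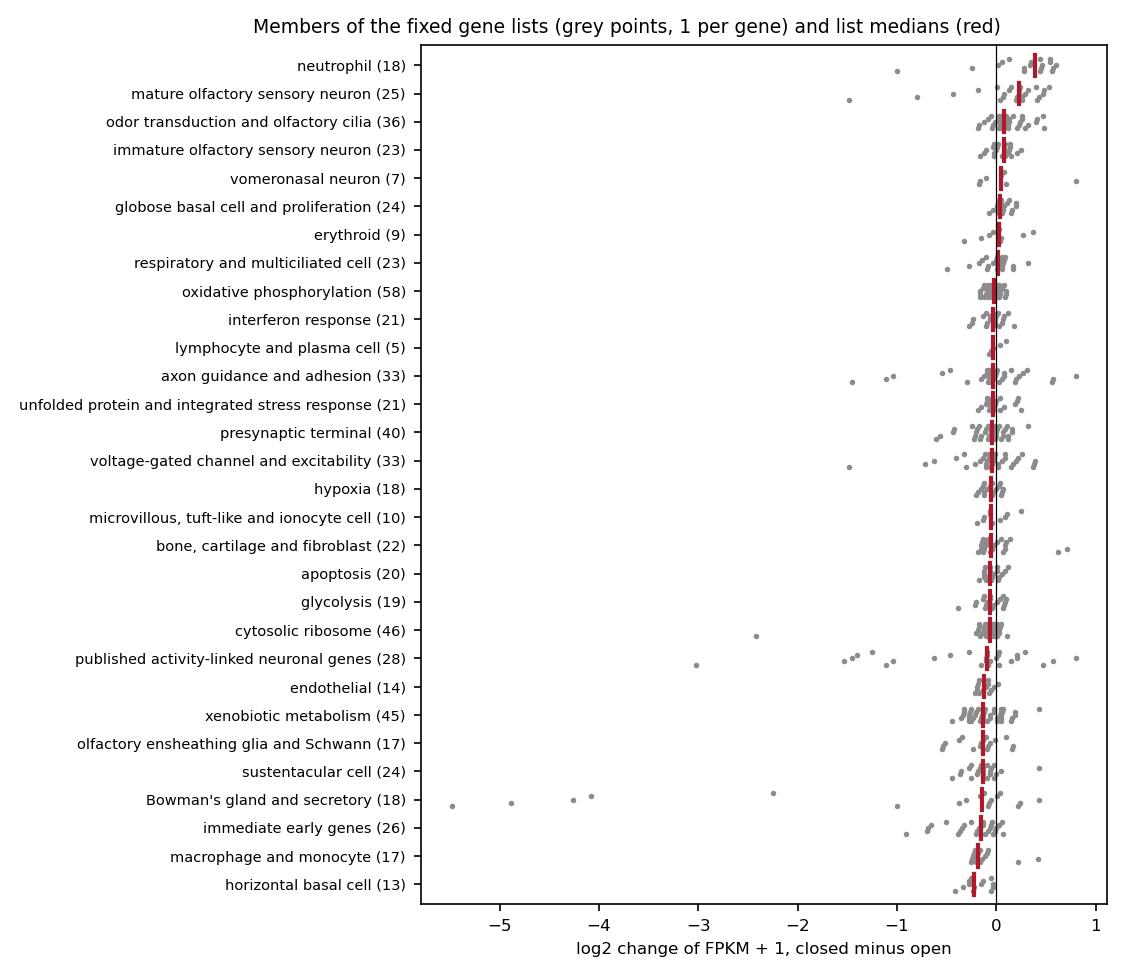
Log2 change of FPKM + 1, closed minus open, for the measured members of 30 fixed gene lists (grey points, 1 per gene) with list medians (red bars) and the number of members in parentheses. Medians lie between -0.22 and 0.39, and the members below -3 are S100a5 among activity-linked genes and Obp1a, Lcn11, Bpifb9a and Bpifb9b among gland genes.

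Olfactory receptor genes, each expressed in a small share of the sensory neurons, gave no call. Of 1085 receptors tested, limma called 0 in either direction, with or without the block. In simulated receptors the test recovered 11.9% of 1.5-fold, 55.2% of 2-fold and 100% of 4-fold changes, so that most 1.5-fold differences would have been missed. At an unadjusted p under 0.05 there were 22 (16 higher and 6 lower on the closed side), and 52 with the block. The first is below and the second close to the share of 0.05 that chance alone would give, a share that holds for the first only if all libraries are independent. The lowest p belonged to Olfr100 (log2 change -1.77, SE 0.51, adjusted p = 0.685), followed by Olfr102 (1.88, SE 0.57, adjusted p = 0.737). In both the sides overlapped, as closed replicate 2 stood at 1.57 FPKM of Olfr100, above every open library (0.853 to 0.961), with the other closed libraries at 0.056 or less, and near 0 for Olfr102, as were 2 open libraries. Olfr855 measured 2.01 ± 0.286 FPKM in closed and 3.97 ± 0.979 FPKM in open libraries (-0.93, SE 0.33), Olfr67 4.28 ± 1.01 against 2.29 ± 0.171 FPKM (0.85, SE 0.32) and Olfr122 2.53 ± 0.325 against 1.34 ± 0.448 FPKM (0.92, SE 0.35), each with an adjusted p of 0.999. At larger pseudocounts of 0.5 and 1, Olfr102 was called higher (adjusted p = 0.0205 and 0.00827, in a range up to 1 over its 15 alternatives). Without closed replicate 2 both Olfr102 and Olfr100 were called (log2 changes 3.21 and -3.02, adjusted p = 0.0245 and 0.0044), and Olfr102 also without open replicate 1 (2.67, adjusted p = 0.0233). Reads shared between similar receptors cannot be separated in FPKM.

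As a family the receptors had a median log2 change of 0.09, with 680 above 0 and 405 below. The 740 receptors at 1 FPKM or more were placed higher by camera at the preset correlation (adjusted p = 9.96e-07), a call lost with an estimated correlation (adjusted p = 0.806) and with the lower side taken without closed replicate 3 (adjusted p = 0.292) or open replicate 2 (adjusted p = 0.545). Summed receptor FPKM were 2154, 1844 and 2703 on the closed and 2185, 1695 and 2314 on the open side of mice 1, 2 and 3, a difference of 168.9 (two-sided exact permutation p = 0.7, the smallest possible being 0.1). The difference took the opposite sign when the sum was divided by Omp (-0.12, exact permutation p = 0.5). The median absolute log2 change was 0.21, above 10000 random sets matched on FPKM, whose median was 0.13. As large a value arose in 7 of the 10 ways to split the 6 libraries 3 against 3, counting the real one. The wide spread of the receptors is therefore no sign of an effect of the side. Among 14 trace amine-associated receptors, 5 were higher and 9 lower on the closed side, led in level by Taar6, which lay outside the naming rule and was named after its values were seen, at 6.69 ± 1.92 and 5.57 ± 1.10 FPKM. Of the vomeronasal receptors, 3 of 205 Vmn1r rows and 4 of 121 Vmn2r rows reached 0.1 FPKM.

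**Figure D3:**
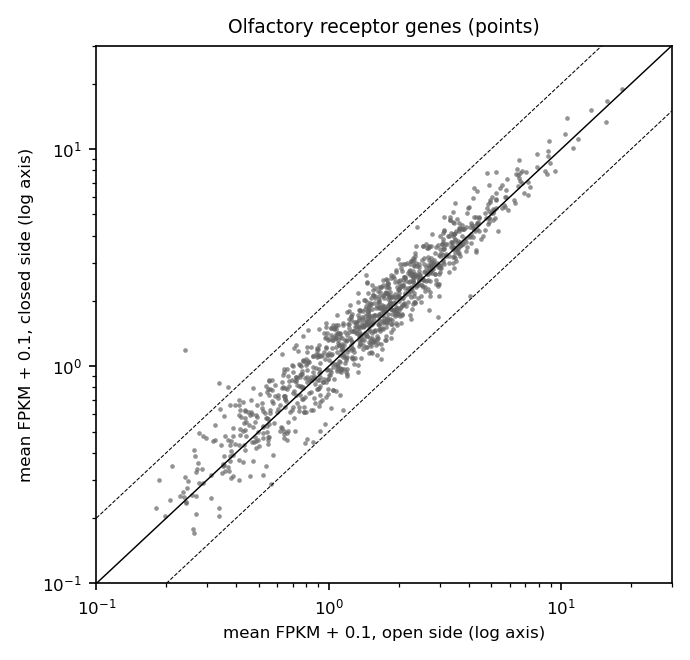
Mean FPKM + 0.1 of 1085 olfactory receptor genes on the open (x axis) and closed (y axis) side, both on log axes, with 3 libraries per mean. The solid line marks equal values and the dashed lines a difference of 2-fold; 680 receptors had a log2 change above 0 and none was past the test.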

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

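S100a5 and Pcp4l1 fell under all 17 alternatives, with log2 changes from -3.17 to -2.91 and from -1.58 to -1.50. Of the 17 alternatives Lrrc3b was called in 6, and of the 16 that gave a value Rasgrp4 was called in 8 and S100a3 in 4, with no change of sign. The alternatives without microRNA and small RNA rows, and those of the trace amine-associated receptors, were chosen after seeing the data, and all others before. The number of rows that fell was 3 with no floor on FPKM, where 20981 rows were tested, and ran from 3 without closed replicate 2 to 10 without closed replicate 3, when Obp1a, Lcn11, Gm14743, Gm14744 and Lcn4 were among the calls (Gm14744 and Lcn4 lay outside the naming rule and were named after their values were seen). The number that rose was 1 to 2 with a library left out, and 0 without small RNA rows, with or without the replicate block, because the row that rose was Mir330. With the replicate block 4 rows fell and 1 rose, Kcnmb3 entering and Lrrc3b, Rasgrp4 and S100a3 leaving, and among lists it added immature neurons (adjusted p = 0.0328) and changed no other call of a whole list or receptor. Apart from the causes named, the cause was not tested.

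The list results rested on the preset correlation, at which the activity-linked, immediate early and gland lists stayed lower and called with each library left out. With an estimated correlation 0 lists were lower and 0 higher, as they were with the directional fry test and with the replicate block and an estimated correlation together. With 1 library left out, 3 (without closed replicate 2) to 9 (without closed replicate 1) lists were higher. The adjusted p of lists that took the other side in at least 1 such fit ranged as follows. Among lists called with all libraries it ran from 4.42e-05 to 0.918 for mature neurons, from 2.2e-18 to 0.545 for receptors, from 2.96e-05 to 0.966 for globose basal cells, from 1.87e-05 to 0.735 for endothelium, from 7.75e-06 to 0.745 for presynaptic genes and from 5.99e-05 to 0.378 for xenobiotic metabolism. Among the others it ran from 7.93e-05 to 0.49 for immature neurons, from 0.000134 to 0.732 for axon guidance, from 6.35e-05 to 0.964 for bone and cartilage, from 1.3e-05 to 0.493 for cytosolic ribosome, from 0.00018 to 0.987 for oxidative phosphorylation, from 0.0309 to 0.958 for erythroid cells, from 0.00332 to 0.753 for glycolysis, from 0.00393 to 0.901 for interferon response, from 0.000405 to 0.794 for multiciliated cells, from 0.0385 to 0.901 for the unfolded protein response, from 0.000105 to 0.844 for voltage-gated channels, from 0.298 to 0.929 for lymphocytes, from 0.203 to 0.895 for microvillous cells and from 0.0932 to 0.702 for vomeronasal neurons. The cause was not tested.

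Choices other than a left-out library ended the calls of endothelium, presynaptic genes, glia and globose basal cells and brought calls of hypoxia and glycolysis, with the values given beside those lists. Some uncalled lists took the other side under a single other choice, in each case without a call. These were, by adjusted p, axon guidance (0.831), erythroid cells (0.831) and interferon response (0.462) at a floor of 5 FPKM, interferon response with no floor (0.859), microvillous cells (0.929), oxidative phosphorylation (0.929) and the unfolded protein response (0.929) with quantile normalization, microvillous cells without the variance trend (0.974) and lymphocytes with fry (0.999). The unfolded protein response did so with the replicate block (0.97), with the block and an estimated correlation (0.998) and with the block and no small RNA rows (0.953), and bone and cartilage with the last of these (0.974). The cause was not tested.

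Among genes in the text with no call, receptors aside, 4 changed sign with a library left out: Bpifb6 ran from -0.040 to 0.196, Gap43 ran from -0.081 to 0.23, Krt5 from -0.21 to 0.12 and Bpifb5 from -3.53 to 0.59. The number of receptors called higher was 1 at pseudocounts of 0.5 and of 1, and 0 to 1 with a library left out, as was the number called lower. The difference in summed receptor FPKM ran from -65.7 (without closed replicate 3) to 363.8 (without closed replicate 2), and divided by Omp it was -0.12. Of the trace amine-associated receptors, 2 (without closed replicate 3) to 9 (without closed replicate 2) lay higher on the closed side. The median absolute change of receptors stayed above its matched random sets in each alternative run. The deposited values hold no counts, so what depth limits could not be separated from the spread of 3 libraries per side, at which simulated 1.5-fold changes were recovered in 38.8% of genes.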

Other observations

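The tests in this part were chosen after the results were seen. Some further genes of secreted proteins, beyond the 4 members named from the fixed gland list, also had large log2 changes, though none was past the test. Of 20 measured genes of the odorant-binding protein, lipocalin, urinary protein, secretoglobin and BPI-fold families, 12 had a log2 change below -1, and 13 were lower on the closed side in 3 of 3 mice, a tally over families picked after 4 of their members had been seen to be low, and so no test. The following genes lay outside the naming rule and were chosen after their values were seen. Scgb2b27 measured 9.40 ± 11.1 FPKM in closed and 109.7 ± 65.9 FPKM in open libraries, Scgb1b27 4.67 ± 3.49 against 77.9 ± 69.5, Lcn4 5.33 ± 6.81 against 38.8 ± 13.8, Lcn3 234.9 ± 230 against 727.9 ± 203 and Obp2a 469.1 ± 452 against 1434 ± 444 (SD, n = 3 each). Mup4, a major urinary protein gene, had a log2 change of -1.76, and 2 secreted enzymes from other families had changes of -3.25 (Klk1, a kallikrein) and -3.18 (Car6, a secreted carbonic anhydrase). No member of the 5 families was past the limma test over all rows, and not every member was lower: the log2 change was 0.09 for Bpifb6, which was higher in 3 of 3 mice but turned negative without closed replicate 3 (-0.040), 0.24 for Bpifb4, 0.28 for Lcn2 and 0.43 for Bpifb3. Bpifb5 had a log2 change of -1.40, but its mean FPKM was higher in closed than in open libraries (193.7 ± 315 against 85.6 ± 52.3), because closed replicate 2 stood at 556.7.

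The fall of S100a5, Pcp4l1, Lrrc3b, Rasgrp4 and S100a3 was weighed against 3 other explanations. A lower number of mature neurons on the closed side would lower their other markers by a similar amount, and the 25 measured markers of the fixed list, none of which is among the 5 genes, had a median log2 change of 0.23, with quartiles of 0.065 and 0.32. The lower depth of closed replicate 1 would bring the changes toward 0 without that library, and the one nearest to 0 among the 5 genes was then still -1.26, although with 5 libraries the calls of Lrrc3b and S100a3 ended (adjusted p = 0.104 and 0.115). As to chance, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 7 called rows, the highest of the others gave 2, and among the 4 splits that part the sides of all 3 mice the real one was again the only one. With small RNA rows kept in each fit but left out of the count, the real split gave 5, the genes named, and each of the other 9 gave 0. Refitted without those rows the real split gave 6, Kirrel2 being added, and the other splits were not refitted. In any case 10 splits are too few for a share under 0.05. A response of neurons to the loss of airflow, which the design names, may account for the pattern and stays open as a hypothesis. Without unoperated mice it cannot be told from a change on the open side.

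The low lipocalin, secretoglobin and BPI-fold transcripts on the closed side were weighed likewise. Less glandular tissue of every kind would lower the other gland genes too, and the 9 measured members of the fixed gland list outside the 5 families had a median log2 change of -0.083, with a lower quartile of -0.16. Among these 9, Sox10, Lyz2 and Ltf are also in the glia, macrophage and neutrophil lists. Klk1 and Car6, secreted enzymes outside the 5 families that were chosen after their values were seen, were far lower. The 9 members thus speak only against a loss shared by all gland genes. A single source recovered in unequal amounts would keep its genes in 1 ratio within a side, but the median pairwise correlation of the 12 genes' deviations from their side means was 0.069 (0.166 without Bpifb5). It lay below the 95th percentile of 0.34 of 10000 random sets of genes at least as variable as the least variable of the 12. That median hides pairs from -0.951 (Bpifb5 and Obp1a) to 0.997 (Lcn3 and Obp2a). These correlations rest on 3 libraries per side, and some genes were near 0 on the closed side, as Bpifb9a and Bpifb9b at 0 in closed replicate 2. A ratio cannot show at such values, so the low median alone cannot exclude a single source. Several glands, each recovered in its own amount, would give many tight pairs, and 8 of the 66 pairs correlated above 0.9. That count lay between the median of 3 and the 95th percentile of 9 of random sets, so that this explanation may still account for the group. A response of gland cells to closure may do so too, as a hypothesis that was not tested.

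The fall of S100a3 may come from S100a5 transcripts counted at this nearby gene. If so the sides would share 1 ratio, and S100a3 stood at 0.199% ± 0.0526 of S100a5 in closed and 0.138% ± 0.00629 in open libraries (SD, n = 3 each), a difference of 0.061 percentage points with overlapping values. Closed replicates 1 and 2 (0.219% and 0.239%) stood above every open library (0.131% to 0.144%), and only closed replicate 3 (0.139%) overlapped. With 3 libraries per side values mostly overlap by chance, so the overlap cannot decide whether the ratio was shared. S100a4, a neighbour on the same strand in the GRCm38 annotation, measured 69.8 ± 13.5 against 88.8 ± 12.0 FPKM and was not past the test. That spread is larger than the S100a3 values themselves, so a gain of their size could not be seen there. Joint regulation of S100a3 and S100a5 predicts the same ratio and stays open.

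The splits also bear on the other counts. For lists, 7 of the 10 splits gave as many as the real 15 called with the preset correlation, and the highest of the others gave 19. Of the 4 splits that part all mice, 3 gave as many, counting the real one, and 10 splits are too few for a share under 0.05. For receptors the real count was 0, so all 10 splits necessarily gave as many and the comparison says nothing; the highest of the others gave 2. The median absolute change of receptors was 0.21 in the real split and as large in 7 of the 10, with 0.37 as the highest. Rows at an unadjusted p under 0.05 numbered 215 in the real split and 41 to 856 in the other 3 splits that part all mice. In splits that place both sides of a mouse together they reached 1955, which points to a structure of the libraries other than the side.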
